A study of Homo sapiens with 6 samples.

How the data were processed

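RNA was sequenced from HaCaT cells, an immortalized line of human skin keratinocytes, transfected either with a plasmid that overexpresses the transcription factor WT1 (n = 3 libraries) or with a blank plasmid (n = 3 libraries, called control). Per the labels' protocols, total RNA was treated with DNase I, ribosomal RNA was removed by an RNase H or Ribo-Zero method, and the libraries were circularised before sequencing. The submitters' processing notes name Trimmomatic, Bowtie2 and RSEM, without versions, and the genome builds GRCh38.p11 and hg38. The strandedness of the counting is not given in the sources used here.

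The deposited expected counts are, per the file headers, the estimated number of reads per gene and per transcript in each library and were not normalized. The deposited FPKM values, per the file headers, are scaled by the authors to feature length and library size. Genes were keyed by NCBI Gene ID and symbol. The gene table of a library lists only genes with an FPKM of at least 0.01, so a gene absent from it was taken as 0; 2541 of the 17693 genes were absent from at least 1 library. FPKM values in the authors' joined table were identical to those of the single libraries. All listed transcripts are protein-coding RefSeq models, so non-coding RNA was not measured here, and the mitochondrially encoded genes were not among the genes listed. The authors also deposited a comparison of the groups by DEGseq, per the file name, with a p-value and a q-value per gene and, in a filtered list, the log2 ratio of the WT1 to the control group; its group values were the sums of the 3 libraries' expected counts to within 1.

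Expected counts were rounded to whole numbers. Counts per library summed to between 17639680 and 17980622. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, two-sided, all 6 libraries, no covariate). Adjusted p-values are Benjamini-Hochberg values over the 13792 genes tested, and a gene was called when its adjusted p was under 0.05. Levels in CPM, the counts scaled to a common library total, are given on the TMM-scaled library sizes as mean ± SD over the 3 libraries of a group, and log2 fold changes are WT1 minus control with their standard error (SE). The SD measures the spread between these libraries. The SE was derived from the edgeR F-statistic, whose dispersion is estimated partly across genes, so it is not the spread of a single gene alone. Nothing in the labels says that replicates came from separate cultures or transfections, so p-values measure only the spread between these libraries, which may be technical. Intervals of count ratios are exact 95% intervals and, like a floor of 3 counts used where a group summed to 0, cover counting error only.

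Gene lists were written before the data were examined: 39 lists with 959 entries, of which 895 were matched to a gene of the files by symbol or synonym. Of these, 35 lists had at least 5 tested members and were tested with camera on voom log-CPM (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 35 lists. Camera with an estimated correlation, and fry, were run beside it. Genes were named by a rule set at the same time: WT1; the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups' libraries; up to 4 members per list with the smallest p; and, from the authors' filtered list, the 3 genes with the largest ratio each way. Gene positions come from GENCODE 29 on GRCh38.

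The tests were tried on simulated data drawn from the real means and library sizes with 200 changed genes. Over 13792 genes simulated for WT1 against control, edgeR recovered 72% of genes changed 1.25-fold, 88% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, and 6 of its 178 calls were false. In the same simulation a list of 30 genes raised 1.5-fold had an adjusted p of 1.2e-112 with the preset correlation and 0.000609 with the estimated one, and 0 of 20 random lists passed with either. Genes were simulated independently of each other, so the random lists do not show how often lists of correlated genes pass. Each recovery rate rests on 50 changed genes. The 200 changed genes were far fewer than the 4301 called in the real data, so these rates need not hold there. No pair of libraries of 1 group agreed within sampling noise: the chi-square per degree of freedom of their counts was between 2.55 and 4.42, and between groups it was at least 13.1.

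Alternatives were DESeq2 1.42.0 with its size factors, upper-quartile factors, library size alone, no count filter, a filter of CPM of at least 1 in 3 libraries, limma-voom, limma on log2(FPKM + 0.1) and log2(FPKM + 1) with a mean FPKM of at least 0.5, limma on log2(FPKM + 0.1) without that filter, a block for the replicate number, a 2-fold minimum, and each library left out in turn. Sums of genes with a near-identical or overlapping partner, gene ontology terms, and the overlap with the authors' list with each library left out were added after the data were seen. Values of some single genes that the naming rule or a list takes in are not reported here.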

Results

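Gene expression was measured by RNA sequencing in HaCaT, a spontaneously immortalized line of human epidermal keratinocytes, after transfection with a plasmid carrying WT1 (n = 3 libraries) or a blank plasmid (n = 3 libraries). WT1 is a zinc-finger transcription factor best known from kidney development and Wilms tumour. The depth was similar in all libraries: the expected counts summed to 17926041, 17802040 and 17980622 in WT1 replicates 1, 2 and 3 and to 17699001, 17647271 and 17639680 in control replicates 1, 2 and 3. KRT14 was the most abundant gene in each WT1 library, with 1.26% to 1.31% of the counts, and KRT5, the other keratin of the basal epidermal layer, in each control library, with 1.43% to 1.51%. The design holds 1 comparison, which asks which genes differ between HaCaT cells given WT1 and cells given the blank plasmid.

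WT1 itself was far higher in the libraries that received its plasmid. WT1 (chromosome 11, 32387775 to 32435630, minus strand, GRCh38) had expected counts of 122.2, 113.0 and 119.0 in WT1 replicates 1, 2 and 3, against 1.0, 0.0 and 0.0 in control replicates 1, 2 and 3. The depth-corrected count ratio was 349, with an exact 95% interval of 62.3 to 1.38e+04, which is wide because the control count is 1. On the TMM scale the level was 6.56 ± 0.224 CPM (SD, n = 3) against 0.0189 ± 0.0328 CPM, with an adjusted p of 5.72e-11 in edgeR. The FPKM was 2.24, 2.19 and 2.18 in the WT1 libraries. The reads were assigned to transcript NM_024424.3, with 122.2, 87.34 and 119.0 expected counts, except for 25.66 counts given to NM_001198551.1 in WT1 replicate 2. The share of each transcript was not tested, since none was found in both groups. In the WT1 libraries 23.5% of the 13792 genes tested had a lower mean CPM than WT1, and the median gene stood at 28.6 CPM.

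All 30 DNA replication genes listed, 15 of 22 NF-kB targets and 13 of 16 feedback genes of the ERK pathway rose in the WT1 libraries, while 18 of 37 genes of epidermal terminal differentiation fell, among them KRT1, KRT10 and DSG1. Of 13792 genes tested, 4301 changed (31.2%), 2285 of them higher and 2016 lower with WT1. Most changes were small: 85.9% of the changed genes differed by less than 1.5-fold, the median fold of changed genes was 1.21, and 151 genes changed at least 2-fold, 81 upward and 70 downward. The 3 WT1 and 3 control values did not overlap for 44.3% of the tested genes, where chance alone gives 10%. In the first principal component, with 49.0% of the variance, the controls lay at 16.5 to 19.7 and the WT1 libraries at -21.6, -12.0 and -20.2, with replicate 2 nearest the controls. The WT1 count of replicate 2 was 0.946 of the mean of the others (exact 95% interval 0.750 to 1.19).

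**Figure D1:**
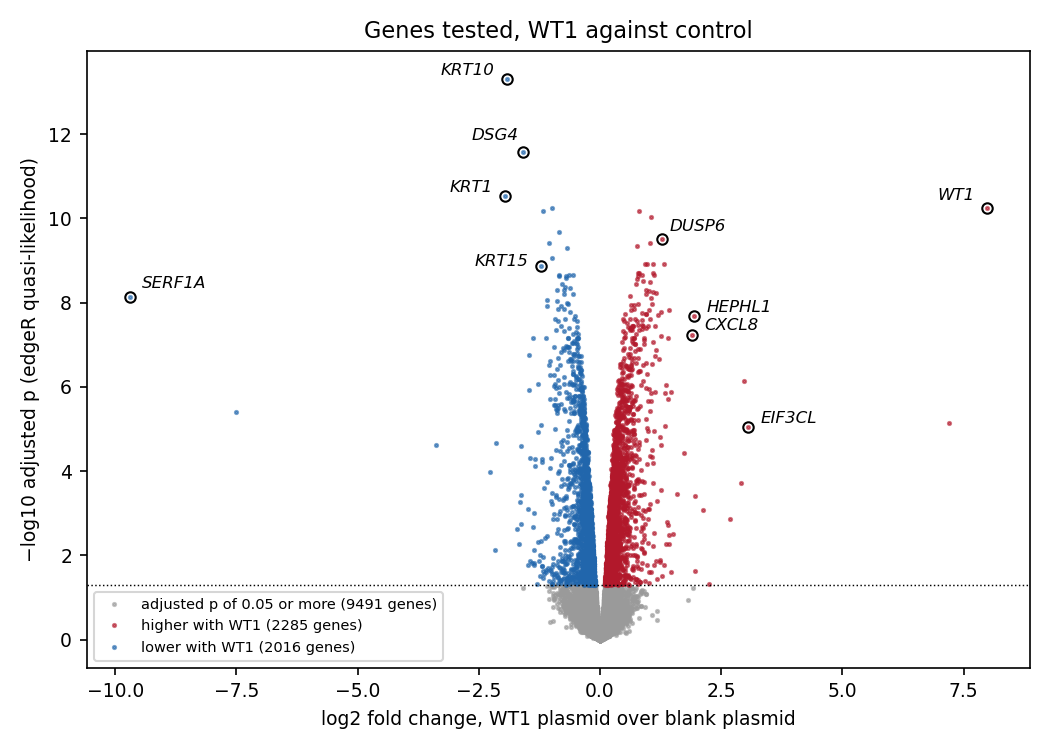
Each point is 1 of the 13792 genes tested, with the log2 fold change of the WT1 over the blank plasmid on the x axis and −log10 of the edgeR adjusted p on the y axis; the dotted line marks an adjusted p of 0.05. The 2285 genes called higher (red) and 2016 called lower (blue) lie mostly within 1 log2 unit of 0, while WT1, SERF1A and EIF3CL stand far outside and KRT10 has the smallest adjusted p.

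The 12 largest rises under the naming rule were EIF3CL, HEPHL1, CXCL8, VEGFC, CDC45, GINS2, IL1A, CXCL1, CYP27B1, IL1R2, DTL and DUSP6. HEPHL1, a copper-dependent ferroxidase, rose 3.83-fold, from 1.88 ± 0.144 to 7.22 ± 0.536 CPM. CXCL8 (chromosome 4, 73740506 to 73743716), a neutrophil chemokine, rose 3.72-fold, from 2.89 ± 0.603 to 10.7 ± 2.11 CPM. The lymphatic growth factor VEGFC rose 2.75-fold, and the alarmin cytokine IL1A rose 2.63-fold, from 4.27 ± 0.229 to 11.2 ± 1.30 CPM. CDC45 (chromosome 22, 19479459 to 19520612) and GINS2, subunits of the replicative helicase, rose 2.68-fold and 2.63-fold; CDC45 went from 11.6 ± 1.69 to 31.0 ± 4.98 CPM. The chemokine CXCL1 rose 2.57-fold, CYP27B1, the enzyme that makes active vitamin D, 2.53-fold, the interleukin-1 decoy receptor IL1R2 2.52-fold, and the ubiquitin ligase subunit DTL 2.49-fold. DUSP6 (chromosome 12, 89347232 to 89353271), a phosphatase of ERK, rose 2.41-fold, from 67.1 ± 1.77 to 162 ± 23.1 CPM. EIF3CL rose 8.25-fold, from 2.01 ± 1.87 to 16.6 ± 7.75 CPM, but it is a near-identical copy of EIF3C and shares reads with it: the summed counts of EIF3CL and EIF3C had a log2 fold change of 0.10 (SE 0.0375, adjusted p = 0.05, just under the threshold). The log2 fold change of EIF3CL was 3.04, and 3.83 without control replicate 1 (range over the alternatives 2.25 to 4.62). DESeq2 gave 3.06 and did not call EIF3CL (adjusted p = 0.139; range over the alternatives 7.31e-09 to 0.139). The adjusted p of the other 11 genes in edgeR was at most 8.69e-06. Each was higher in 3 of 3 WT1 libraries than in any control, which the naming rule requires.

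The 12 largest falls were SERF1A, KRT1, KRT10, JMJD7-PLA2G4B, DSG1, DSG4, FABP4, KCNH4, PHGR1, PDE3A, CLCA4 and FSTL4. KRT1 (chromosome 12, 52674736 to 52680407) and KRT10 (chromosome 17, 40818117 to 40822595), the keratin pair of the suprabasal epidermis, were 3.89-fold and 3.79-fold lower. KRT1 went from 478 ± 48.4 to 123 ± 23.5 CPM and KRT10 from 657 ± 33.2 to 173 ± 19.3 CPM, with edgeR adjusted p-values of 2.9e-11 and 4.89e-14. The desmosomal cadherins DSG1 and DSG4 were 3.08-fold and 3.03-fold lower, DSG4 at 37.0 ± 2.96 against 112 ± 9.48 CPM. The fatty acid carrier FABP4 was 2.77-fold lower, the potassium channel gene KCNH4 2.77-fold, PHGR1 2.71-fold, the phosphodiesterase gene PDE3A 2.63-fold, CLCA4 2.53-fold and FSTL4 2.52-fold lower, with adjusted p-values of at most 7.53e-05. SERF1A (chromosome 5, 70900665 to 70918530) had 0 counts in all WT1 libraries against 309 in the controls, at least 104-fold lower against a floor of 3 counts over the group. It shares reads with its copy SERF1B (chromosome 5, 70025247 to 70043113), and their sum had a log2 fold change of -0.12 (SE 0.0747, adjusted p = 0.253). JMJD7-PLA2G4B is a read-through of adjoining genes; summed with JMJD7 and PLA2G4B its log2 fold change was 0.07 (SE 0.0617, adjusted p = 0.456). DESeq2 (adjusted p = 0.108) and limma on unfiltered log2(FPKM + 0.1) (adjusted p = 0.0609) did not call it, with a range over the alternatives of 9.19e-06 to 0.108. These sums were chosen after the values were seen.

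**Figure D2:**
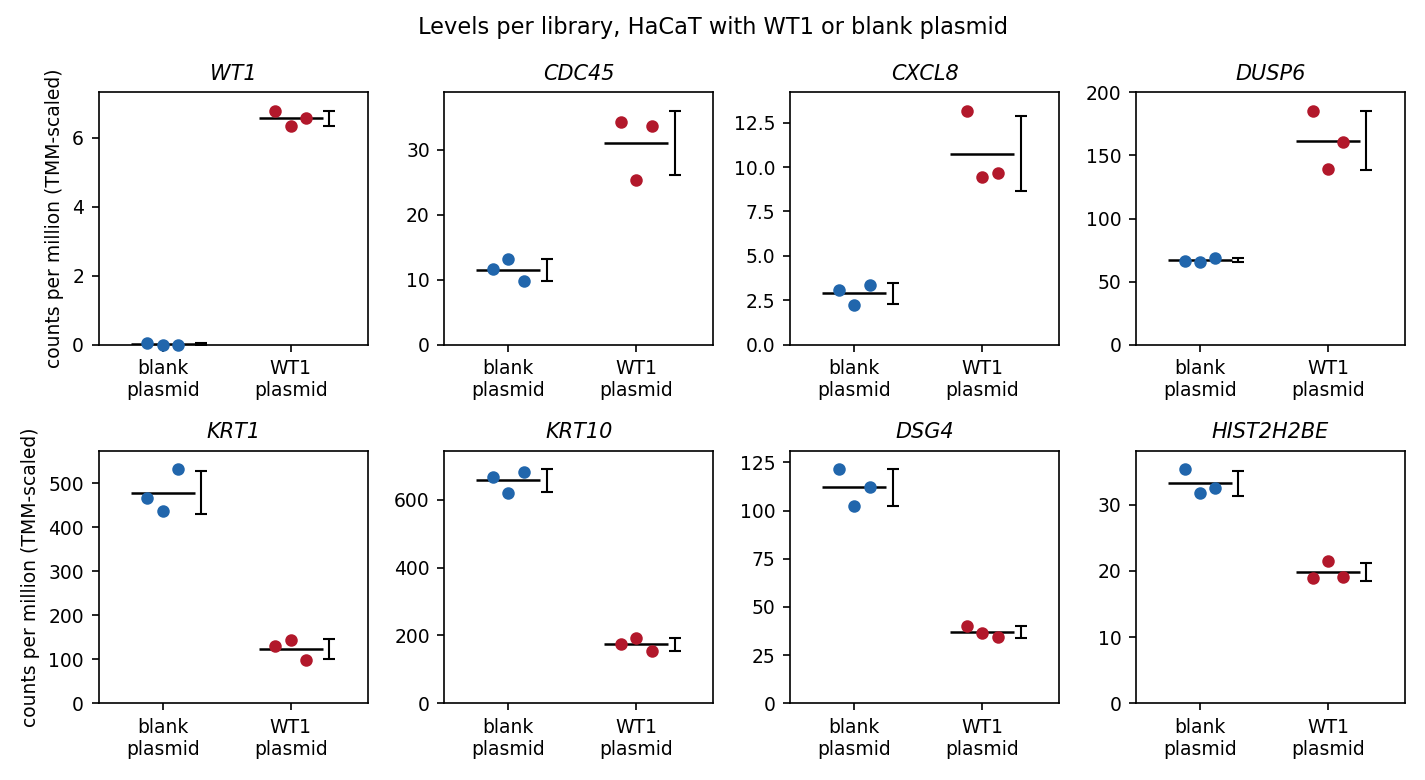
Level in CPM (TMM-scaled, y axis from 0) of 8 genes in each library of the blank plasmid (blue) and the WT1 plasmid (red); lines are means and bars SD over 3 libraries. WT1, CDC45, CXCL8 and DUSP6 are higher and KRT1, KRT10, DSG4 and HIST2H2BE lower in each of the 3 WT1 libraries than in any control.

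Genes of DNA replication and mitosis were higher with WT1. All 30 members of the DNA replication list rose, also when adjusted over the list alone, with a median log2 fold change of 0.76 and values from 0.20 to 1.42. The ribonucleotide reductase subunit RRM2 rose 2.12-fold, from 47.6 ± 3.19 to 101 ± 12.4 CPM, the origin licensing factor CDC6 2.15-fold, from 31.3 ± 4.89 to 67.1 ± 5.05 CPM, and the helicase subunits MCM2 and MCM6 2.11-fold and 1.94-fold. Of 30 mitosis and cell cycle genes, 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.28; CDC20, an activator of the anaphase-promoting complex, rose 1.38-fold, the kinase gene AURKB 1.37-fold and the transcription factor gene FOXM1 1.30-fold. The camera adjusted p was 7.53e-26 for replication and 9.29e-11 for mitosis with the preset correlation, and the adjusted p with an estimated correlation was 0.265 and 0.382. Of 14 tested genes on the list of replication-dependent histones, which encode core and linker histones, 0 rose and 9 fell (12 adjusted over the list alone), with a median of -0.60 and a camera adjusted p of 1.92e-06 (adjusted p = 0.265 with an estimated correlation). HIST2H2BE was 1.67-fold lower, HIST1H2BD 1.57-fold and HIST1H2AC 1.82-fold lower. Members of this family are near-identical, so single genes are uncertain; the summed counts of all 62 genes named HIST were 4308 ± 186 against 5759 ± 72.8 per library, a log2 fold change of -0.45 (SE 0.0415).

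Genes of epidermal differentiation, cell junctions and lipid synthesis were lower on balance. Of 37 terminal differentiation genes, 1 rose and 18 fell, with the same counts adjusted over the list alone and a median of -0.22 (camera adjusted p = 4.02e-07; adjusted p = 0.265 with an estimated correlation). Besides KRT1 and KRT10, the lipid transporter gene ABCA12 was 1.55-fold lower, at 26.4 ± 0.780 against 40.9 ± 1.47 CPM, and the cornified envelope gene SPRR1B 1.52-fold lower. Of 28 epithelial junction genes, 5 rose and 15 fell, again with the same counts adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.00103; adjusted p = 0.265 with an estimated correlation). The members with the smallest p were desmosomal: DSC2 was 1.62-fold lower, DSG3 1.54-fold, DSC3 1.42-fold and PERP 1.39-fold lower, and DSG3 went from 1513 ± 61.0 to 982 ± 51.7 CPM. Desmosomal cadherins did not all fall: of members named after their values were seen, DSG2 rose, at 476 against 437 CPM, and DSC1 was not called, at 1.61 against 1.67 CPM (edgeR adjusted p = 0.903). Of 29 genes of cholesterol and fatty acid synthesis, 4 rose and 13 fell (5 and 13 adjusted over the list alone; median -0.13; camera adjusted p = 0.0116; adjusted p = 0.265 with an estimated correlation). The desaturase gene SCD was 1.73-fold lower and INSIG1, a sterol-regulated retention factor, 1.58-fold lower. Among 30 nuclear genes of oxidative phosphorylation 2 rose and 10 fell (3 and 10 adjusted over the list alone; median -0.08; camera adjusted p = 0.0224; adjusted p = 0.382 with an estimated correlation), with NDUFB5 1.19-fold and COX6C 1.18-fold lower; without control replicate 2 the camera adjusted p of this list was 0.0902, in a range over the alternatives of 0.0129 to 0.0902.

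Lists of NF-kB targets, of keratinocyte cytokines and of antimicrobial peptides passed upward, although not all of their members rose. Of 22 NF-kB targets, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 5.54e-08; adjusted p = 0.265 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, rose 2.07-fold, and the subunit gene NFKB2 1.58-fold, from 53.2 ± 1.74 to 84.1 ± 7.57 CPM. Of 20 keratinocyte cytokines and chemokines, 12 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.85 (camera adjusted p = 0.000171; adjusted p = 0.265 with an estimated correlation). IL1B rose 2.05-fold, from 19.4 ± 1.84 to 39.7 ± 4.66 CPM, and CCL5 1.71-fold, while IL18, IL15 and IL1RN, named after their values were seen, fell. Of 15 antimicrobial peptides and alarmins, 6 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.18; camera adjusted p = 0.0220; adjusted p = 0.382 with an estimated correlation); the calprotectin subunit gene S100A9 rose 1.56-fold, LCN2 1.79-fold and PI3 1.65-fold. That list missed the threshold without WT1 replicate 2 (camera adjusted p = 0.133) and without control replicate 2 (0.0714), in a range over the alternatives of 0.0028 to 0.133, and without control replicate 3 its median was 0.27.

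Lists tied to growth-factor signalling and WT1 also passed upward with the preset correlation. Some lists share genes, so their calls are not all separate findings. Of the tested members, 12 immediate early genes, 7 ERK feedback genes and 7 NF-kB targets stand on another list. PHLDA1, FOSL1 and IER3 count in both the ERK and the immediate early lists. CXCL8 and CXCL1 count in both the NF-kB and the cytokine lists. Of 16 feedback genes of the ERK pathway, 13 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.60 (camera adjusted p = 5.54e-08; adjusted p = 0.275 with an estimated correlation). Beside DUSP6, PHLDA1 rose 1.90-fold, from 116 ± 3.47 to 221 ± 23.9 CPM, and FOSL1, an AP-1 subunit gene, 2.03-fold. Of 13 EGFR ligands and receptors, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.43, which was 0.22 without WT1 replicate 3 (camera adjusted p = 0.00197; adjusted p = 0.265 with an estimated correlation). The ligand genes AREG, TGFA, HBEGF and NRG1 rose 2.16-fold, 1.75-fold, 1.66-fold and 1.44-fold, and TGFA went from 62.3 ± 2.71 to 109 ± 7.56 CPM. Of 28 immediate early genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.16; camera adjusted p = 8.71e-05; adjusted p = 0.382 with an estimated correlation), among them EGR1, which rose 1.68-fold. Of 18 YAP/TAZ targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.24; camera adjusted p = 8.67e-07; adjusted p = 0.265 with an estimated correlation); the tissue factor gene F3 rose 2.04-fold, from 526 ± 52.4 to 1070 ± 73.1 CPM, and CYR61 2.05-fold. Of 29 genes reported elsewhere as WT1 targets, 10 rose and 3 fell, with the same counts adjusted over the list alone (median 0.11; camera adjusted p = 0.00313; adjusted p = 0.382 with an estimated correlation). Its strongest members, DUSP6, AREG, EGR1 and MYC, all rose, MYC by 1.54-fold, and 18 of its tested members stand on other lists too. The test took no account of whether WT1 was reported to raise or lower each gene. A rise of the list thus does not show that these genes followed their reported directions.

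Glycolysis and chaperone genes completed the lists that passed. Of 29 hypoxia and glycolysis genes, 20 rose and 2 fell (21 and 3 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 2.68e-06; adjusted p = 0.382 with an estimated correlation). The glucose transporter gene SLC2A3 rose 1.99-fold, from 9.31 ± 2.11 to 18.5 ± 1.21 CPM, ANGPTL4 2.15-fold and the phosphofructokinase gene PFKP 1.30-fold. Of 16 heat shock genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.16; camera adjusted p = 0.00398; adjusted p = 0.382 with an estimated correlation); HSPA8 rose 1.31-fold and HSP90AB1 1.22-fold, while the small heat shock protein gene HSPB1 was 1.26-fold lower. In all, 17 of the 35 lists tested passed with the preset correlation, 12 higher and 5 lower. With an estimated correlation 0 passed, 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.265. In fry, which does not compare a list with other genes, 21 passed, but hypoxia and glycolysis did not (fry adjusted p = 0.0825). Fry also passed p53 targets and podocyte and kidney development genes, both downward. It passed simple epithelial keratins, matrix proteases and inhibitors, and mesenchymal genes as well, all upward.

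**Figure D3:**
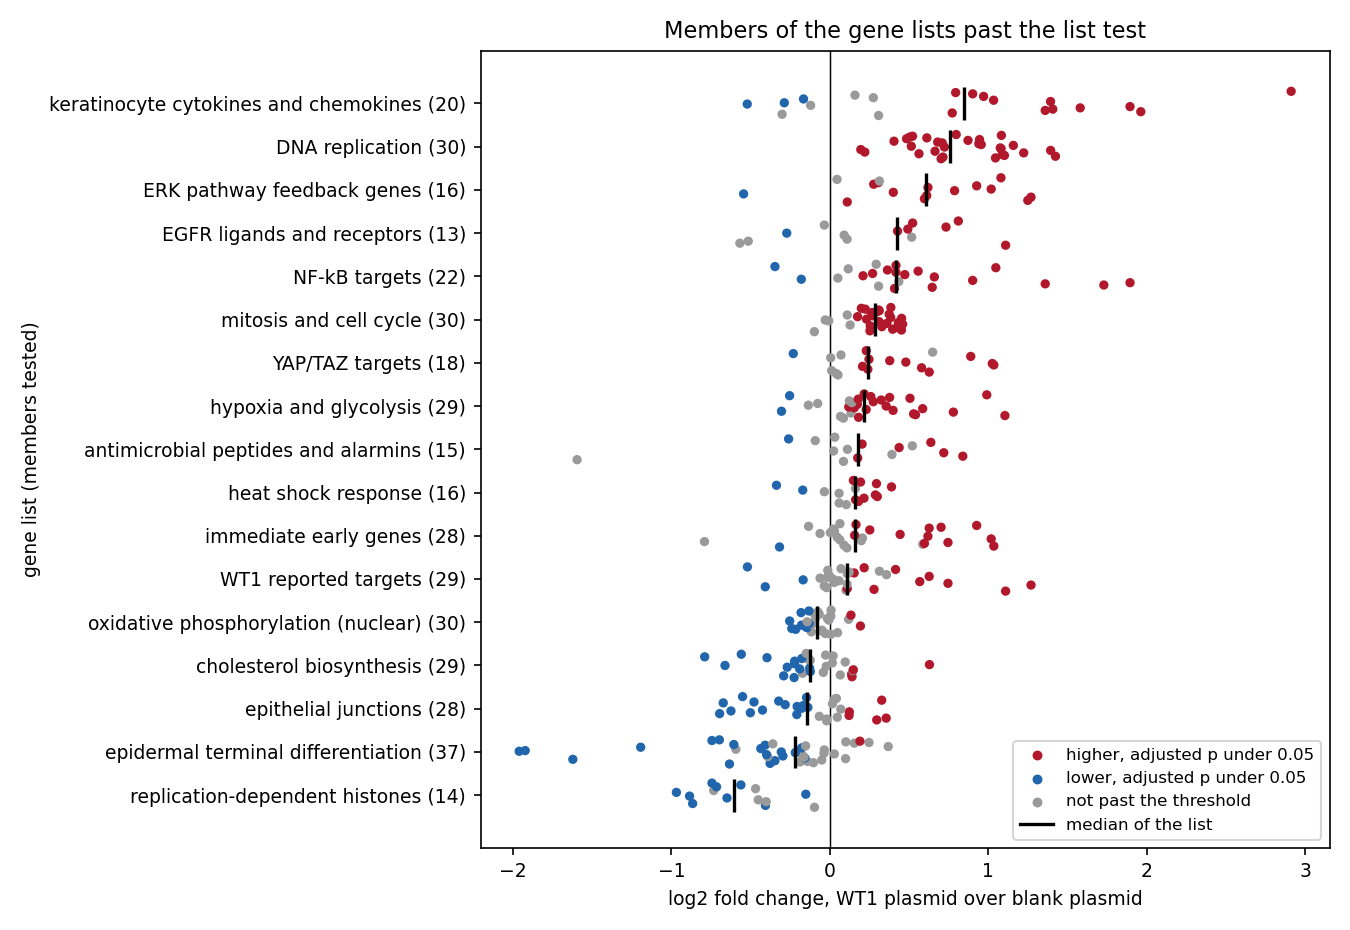
Log2 fold changes (x axis, WT1 over blank plasmid) of the tested members of the 17 gene lists past the list test, 1 row per list with the number tested; red and blue points are genes called higher and lower by edgeR, grey points were not called and black bars are medians. The medians run from -0.60 for replication-dependent histones to 0.85 for keratinocyte cytokines and chemokines, and no grey point lies in the DNA replication row.

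In the authors' full comparison, before any fold minimum, 4618 genes had a q-value of 0.001 or less. Their filtered list holds 181 genes as differential, 102 higher and 79 lower, all with an absolute log2 ratio of at least 1 and a q-value of at most 0.000981. Of these, 138 were tested here, edgeR called 133, and all 133 had the same direction; 5 were tested and not called, and 43 did not pass the count filter. Another 23 genes called here with at least a 2-fold change are not in that list. Both analyses use the same 6 libraries, so the overlap (odds ratio 60.6, Fisher's exact test p = 7.6e-61, two-sided) is not independent evidence. In the authors' deposited table the largest positive log2 ratios belong to MTPN (9.31), WT1 (8.45) and PLGLB1 (7.09). All 322 rounded counts of MTPN came from WT1 replicate 1, with 0 in the other 5 libraries, and those of PLGLB1 were 37, 0 and 32 in the WT1 libraries and 0 in the controls; neither MTPN nor PLGLB1 passed the count filter here. The ratio of MTPN thus rests on 1 library, and whether its reads are shared with a read-through or overlapping gene was not settled, so it is uncertain. The largest negative ratios in the authors' deposited table belong to SERF1A (-9.29), LOC107987477 (-8.60) and TRIM6-TRIM34 (-7.09), a read-through of adjoining genes. LOC107987477 had 96, 42 and 0 counts in control replicates 1, 2 and 3 and 0 in the WT1 libraries.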

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

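The overlap counts with a library left out and the sums with partner genes were chosen after the data were seen. The direction of WT1 and its side of the threshold held in all 16 alternatives, with log2 fold changes of 1.67 to 9.87; the lowest come from log2(FPKM + 1), where the pseudocount shrinks a gene of low FPKM, and the highest is without control replicate 1, the control library that holds the 1 WT1 count. The number of genes changed, WT1 against control, was 4301 in the main test, 3178 to 4318 with other scalings, filters, tests and units and 3243 to 4332 with 1 library left out, and 4303 with SERF1A, EIF3CL and JMJD7-PLA2G4B summed with their partners. DESeq2 called 3390 genes, of which 3384 were also called by edgeR. Outside a factor of 1.5 were the 1240 lower genes (2016 in edgeR) from limma on unfiltered log2(FPKM + 0.1), for which the cause was not tested, and the 151 genes left by a 2-fold minimum, which follows from that minimum. The share of higher genes, 53.1% in the main test, was 51.1% to 61.0% elsewhere. With a replicate block in edgeR 4120 genes were called, 4064 of them also called without it, and 18 lists passed, mesenchymal genes being added. Libraries with the same number had deviations that correlated by 0.0868, -0.00701 and 0.0237. These values give no sign that the numbers pair the samples, but a weak pairing could go unseen. Of the gene lists, 17 passed with the preset correlation, 17 with library size alone, 21 in fry, 15 to 20 with 1 library left out and 0 in camera with an estimated correlation, where 4 had an unadjusted p under 0.05. That correlation was 0.725 for DNA replication but -0.0252 for cholesterol biosynthesis, below the preset 0.01. The unadjusted camera p of cholesterol biosynthesis still rose from 0.00496 to 0.0336, and the list lost its call. Correlation between its genes thus does not account for that loss, and the whole cause was not tested. A miss with an estimated correlation therefore does not show by itself that correlated genes produced a list's call. The overlap with the authors' list was 133 genes, 102 with DESeq2 and 131 to 145 with 1 library left out. Of 158 other genes named by the rule, 142 kept their direction and their side of the threshold in each alternative that could test them. By the direction of the camera test rather than the sign of the median, so did 27 of the 35 lists with library size alone, the replicate block and each library left out. Directions changed, with 1 library left out, for results that had not passed: the log2 fold change of TIE1 ran from -0.48 to 0.24, the median of antigen presentation genes from -0.0113 to 0.0546, that of basal keratinocyte and hemidesmosome genes, whose test changed direction, from 0.0232 to 0.0659, and that of collagens and matrix, which changed sign with library size alone as well, from -0.0647 to 0.0437. The median of Notch pathway genes, which had not passed either, ran from -0.0743 to 0.00628 over the alternatives, while its test kept its direction. The cause was not tested. Depth limits genes near the count filter, such as TIE1 at 0.742 CPM in the WT1 libraries, where fold changes of these sizes were not detectable.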

Other observations

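The gene ontology terms, the test on library scaling, the test on histone capture and the sums of genes with their partners were chosen after the results they bear on were seen. Among 1195 gene ontology terms attached to the genes in the files, 54 held more of the higher genes than the 18.6% of the 10480 annotated and tested genes (hypergeometric test, which takes genes as independent and so does not measure the spread between libraries). Beyond replication they included DNA repair, with 60 of 148 genes higher (adjusted p = 4.04e-08), assembly of nucleosomes with the centromeric histone CENP-A, with 17 of 22 (adjusted p = 3.89e-07), cytokine-mediated signalling, with 38 of 89 (adjusted p = 8.71e-06), and glycolysis, with 17 of 30 (adjusted p = 0.000223). Among the lower genes 1 term passed, nucleosome assembly, with 20 of 53 genes lower (adjusted p = 0.0485); keratinocyte differentiation had 11 of 34 genes lower and did not pass (adjusted p = 0.419).

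The other 18 lists tested did not pass with the preset correlation (camera adjusted p from 0.0644 to 0.908), and in most of them members went both ways. Counts are the same adjusted over the list alone unless given, and members beyond the 4 with the smallest p of a list were chosen after their values were seen. Of 22 basal keratinocyte and hemidesmosome genes 7 rose and 7 fell: the laminin chain gene LAMA3 rose 1.42-fold while KRT15, a keratin of basal cells, was 2.33-fold lower, from 1117 ± 89.1 to 479 ± 78.4 CPM (SD, n = 3). Of 6 simple epithelial keratins KRT18 (1.69-fold), KRT8 (1.41-fold) and KRT7 rose, and KRT20 (2.32-fold lower), KRT19 (1.26-fold lower) and KRT23 fell, 3 each way. Of 6 stress and wound keratins 2 rose, KRT17 (1.29-fold) and KRT6B, and 2 fell, KRT6C (1.87-fold lower) and KRT6A; the KRT6 genes are near-identical and share reads, so they are uncertain. KRT6A lost its call in limma on unfiltered log2(FPKM + 0.1) (adjusted p = 0.17; range over the alternatives 0.000388 to 0.17), and KRT6B in that test (0.0878), in DESeq2 (0.0519), without WT1 replicate 1 (edgeR adjusted p = 0.27) and without control replicate 1, 2 or 3 (0.0883, 0.145 and 0.0617), in a range over the alternatives of 0.0153 to 0.27. Of 21 matrix proteases and inhibitors 7 rose and 1, MMP13, was 2.14-fold lower; SERPINE2 rose 2.41-fold, ADAM8 1.92-fold and PLAT 1.58-fold. Of 16 mesenchymal genes 5 rose, among them THBS1 (1.96-fold), ITGA5 (1.64-fold), TNC and TGFBI, and 1 fell, S100A4. Of 24 collagen and matrix genes 4 rose (COL4A2, COL4A1, LAMB1 and COL16A1) and 5 fell (BGN, COL3A1, NID1, COL4A5 and COL4A6). Of 24 p53 targets 5 rose (AEN, BAX, FAS, TNFRSF10B and PLK3) and 9 fell, the cell cycle inhibitor gene CDKN1A being 1.33-fold and TP53INP1 1.65-fold lower. Of 27 apoptosis regulators 9 rose and 6 fell (12 and 7 adjusted over the list alone), with BIRC3, an inhibitor of apoptosis, 1.57-fold higher and BMF, a promoter of it, 1.57-fold lower. Of 18 TGF-beta targets 8 rose, among them TIMP1 (1.46-fold), and ID3, ID2, ID1 and SMAD7, 4 genes, fell (9 and 5 adjusted over the list alone), ID3 at 274 ± 11.6 against 437 ± 3.52 CPM. Of 16 podocyte and kidney development genes, a list chosen because WT1 acts there, 3 rose, VEGFA, PODXL and SIX2, and 4 fell, among them BMP7 (1.47-fold lower), WNT4 and HOXD11. Of 16 Notch pathway genes 3 rose (DLL1, JAG2 and HES4) and 4 fell (HES2, 1.58-fold lower, NOTCH3, NRARP and HEY2), and of 15 Wnt targets 7 rose, MYC by 1.54-fold, and 4 fell (APCDD1, 1.38-fold lower, FZD6, WNT4 and WNT10A). Of 20 NRF2 targets and metallothioneins MT2A (1.46-fold), TXNRD1, NQO1, ABCC3 and OSGIN1 rose, 5 genes, and 6 fell (7 and 6 adjusted over the list alone), with AKR1C1 1.31-fold lower. Of 27 genes of the unfolded protein and integrated stress response 11 rose, SHMT2 by 1.24-fold, and 5 fell (11 and 6 adjusted over the list alone), HERPUD1 (1.42-fold lower), DDIT3, CHAC1, ATF4 and SESN2. Of 47 interferon-stimulated genes 15 rose and 8 fell, IFI27 being 1.70-fold higher and RSAD2 1.55-fold lower; this list passed without WT1 replicate 1 (camera adjusted p = 0.0364) and without control replicate 1 (0.0331), in a range over the alternatives of 0.0331 to 0.821. Matrix proteases passed without control replicate 1 (0.0255; range 0.0255 to 0.152), and mesenchymal genes with the replicate block (0.038), without WT1 replicate 2 (0.0481) and without control replicate 1 (0.0368; range 0.0368 to 0.198). Of 19 antigen presentation genes 3 rose, TAPBP, HLA-F and TAP1, and 1 fell, HLA-DRA, 1.19-fold lower; TAPBP, HLA-F and TAP1 each lost the call without control replicate 2 (edgeR adjusted p = 0.0593, 0.0756 and 0.104; highest over the alternatives 0.0733, 0.0756 and 0.147, lowest 0.00735, 0.00912 and 0.00808), TAPBP also without control replicate 1 (0.0733) and TAP1 also without WT1 replicate 3 (0.147), without control replicate 3 (0.141) and in limma on log2(FPKM + 0.1), filtered (0.0762) or not (0.138), and on log2(FPKM + 1) (0.0751). Of 40 cytosolic ribosomal protein genes 1 rose, RPL35, and 1 fell, RPLP1 (0 and 0 adjusted over the list alone); RPL35 lost the call with the replicate block (edgeR adjusted p = 0.0905) and with upper-quartile factors (0.0688), both lost it in limma on unfiltered log2(FPKM + 0.1) (0.128 and 0.21), and both lost it without WT1 replicate 1, among other libraries (edgeR adjusted p = 0.107 and 0.123; ranges over the alternatives 0.0149 to 0.134 and 0.00521 to 0.21). RPS27 was called lower with the replicate block (0.039), without WT1 replicate 2 (0.0118) and without control replicate 1 (0.025; range 0.0118 to 0.291), and RPS28 lower without WT1 replicate 3 (0.0243; range 0.0243 to 0.357). Median, mean and test differed in sign for antigen presentation (median 0.02, mean -0.02, test upward), basal keratinocyte genes (0.03, -0.04, downward), immune cell markers (0.08, -0.06, downward) and simple epithelial keratins (-0.03, -0.08, upward). Over the alternatives the median of immune cell markers ran from 0.0126 to 0.14 and that of simple epithelial keratins from -0.046 to -0.00315, and the medians of collagens and of matrix proteases changed sign between scalings. Among markers of other cell types, of 7 immune cell markers 0 rose and 2 fell, HLA-DRA and ITGAM, the latter 1.89-fold lower at 6.59 ± 0.610 against 12.5 ± 1.27 CPM. Calls gained upward were CD68 with library size alone (adjusted p = 0.0442), without WT1 replicate 3 (0.0409) and without control replicate 3 (0.0346; range over the alternatives 0.0346 to 0.351), and LYZ without WT1 replicate 2 (0.0485) and in limma with a mean FPKM of at least 0.5 on log2(FPKM + 0.1) (0.0399) and log2(FPKM + 1) (0.0376; range 0.0376 to 0.323). Of 4 endothelial markers VWF changed, 1.76-fold lower, at 3.99 ± 0.209 against 7.01 ± 0.0873 CPM, and of 3 melanocyte markers 0 passed, although PMEL did, downward, without control replicate 3 (log2 fold change -0.71, adjusted p = 0.0353; range 0.0353 to 0.402). Of 3 fibroblast markers COL3A1 was called at 0.611 ± 0.0917 against 1.19 ± 0.296 CPM, a call that was lost without WT1 replicate 1 (adjusted p = 0.0934), WT1 replicate 2 (0.077), control replicate 1 (0.0949) or control replicate 2 (0.122) and in limma on unfiltered log2(FPKM + 0.1) (0.0757), in a range over the alternatives of 0.0194 to 0.122. The mitochondrially encoded genes had no member in the files.

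The first pattern, among 4301 changed genes, is the rise of 30 of 30 DNA replication genes beside the fall of 18 of 37 terminal differentiation genes; with an estimated correlation neither list passed (adjusted p = 0.265 for each), and the ontology term keratinocyte differentiation did not pass either. The choice among 4 library scalings is argued against as the cause, since the lowest median log2 fold change of the DNA replication list over them was 0.754. The median of the terminal differentiation list stayed between -0.224 and -0.203. These scalings hardly differed, with TMM factors of 0.9904 to 1.009, so a shift that they all share was not tested. The real grouping gave 4301 genes and the highest of the other splits 1, so that 1 of 10 splits gave as many. For lists past the threshold the real grouping gave 17, and another split, of WT1 replicates 1 and 3 with control replicate 1, also 17 (2 of 10). In each split but the real one, WT1 and control libraries are unequally shared between the sides, so part of the group difference stays in it. These splits thus do not show the numbers expected without a group difference, and 10 splits are too few for a share under 0.05. A culture state such as density, passage or day that differed between the groups cannot be told apart from an effect of WT1, because the labels give none of these. Deviations of libraries with the same number (lowest correlation -0.00701) gave no sign of shared batches but cannot exclude them. Both an effect of WT1 and such a culture difference may raise replication genes and lower KRT1 and KRT10, and both stay open.

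The second pattern is that histone genes listed as replication-dependent were lower while DNA replication genes were higher. Reads shared between near-identical histone genes are argued against as the whole cause, since the summed counts of all HIST genes still had a log2 fold change of -0.454 (SE 0.0415, adjusted p = 9.71e-08 in edgeR). The values needed by an explanation in which histone mRNAs without a poly(A) tail were hardly captured are there: 5 histone genes of S phase, HIST1H4C among them, summed to between 0.445 and 1.30 CPM per library, and HIST1H4C had at most 6 counts, although the labels describe removal of ribosomal RNA and no selection of poly(A). A candidate explanation is therefore that the fall concerns the polyadenylated histone transcripts that remain, such as HIST2H2BE and HIST1H2BD, and says nothing of histone production in S phase. Whether WT1 lowers those transcripts was not tested apart from the group difference.

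The third pattern is that SERF1A, EIF3CL and JMJD7-PLA2G4B stand among the largest changes. With each summed with its near-identical or overlapping partner, the largest absolute log2 fold change of the 3 sums was 0.118. Part or all of each change may come from how RSEM divided shared reads between copies. The sums cannot decide this, because a partner with many more counts would hide a real change of the smaller gene. The sum of EIF3CL and EIF3C still passed narrowly (log2 fold change 0.10, adjusted p = 0.05 in edgeR). No biological explanation was tested; a shift between the copies themselves stays open, since the files hold no reads to separate them.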
